A study of Saccharolobus islandicus REY15A with 6 samples.

How the data were processed

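RNA of 6 samples of Saccharolobus islandicus REY15A was sequenced, 3 of the CCTF1 overexpression strain and 3 of the strain with the empty plasmid, both under arabinose. Groups and replicate numbers come from the sample titles. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

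The read counts per gene are those the authors deposited, whole numbers with no normalization, per the file headers. HISAT2 2.0.5 is named per the submitters' processing notes. The read counter, its strand setting and its treatment of reads with several matches are not given in the sources used here. The extraction protocol in the labels speaks of retinas and the processing notes name a mouse genome build, whereas the file coordinates are those of the REY15A chromosome. Of the 2721 gene identifiers, 2687 matched the reference gene table (assembly ASM18955v1), and 2682 of these had the same start and end there. Gene names and products come from the file, and older locus tags (SiRe numbers) from the reference table, since 1 older tag is repeated in 105 lines of the file. The authors deposited further columns in the same table, per the file headers: counts divided by a size factor per library, a log2 fold change, and unadjusted and adjusted p-values, with no value for 96 genes. From these only the fold change and the adjusted p-value are used, as the authors' deposited table. The file also holds 6 per-sample columns that belong to no sample of the series and were not used. No deposited FPKM was used here. Where FPKM are mentioned they were computed from the counts, the gene lengths and the library totals.

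Total counts ranged from 2891373 to 3691143 per library. A single gene, SiRe_1612, annotated as a hypothetical protein, took 15.6 ± 1.05% of the counts in CCTF1_OE and 16.2 ± 1.68% in control (mean ± SD, n = 3). Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 13.4 to 101, so no library was treated as a copy of another.

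Genes were kept by filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with group as the only term, on the 6 libraries. P-values were adjusted by Benjamini-Hochberg over the 2409 genes tested, and an adjusted p under 0.05 counts as a call. In gene lists, a count adjusted over the list alone uses only the members' p-values. Standard errors come from the fitted coefficient and its F statistic. CPM are edgeR's cpm values on TMM-scaled library sizes. There were 25 gene lists, fixed before the data were examined as patterns on product names, gene names and locus tags. A list was tested with camera (limma 3.58.1, inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 25 lists. Beside it, camera with an estimated correlation and fry were run. In 4 lists the set test passed, and none of the 4 passed with an estimated correlation. SiRe_1877 was left out of the list of UV-inducible pili because its product is an RNA methyltransferase.

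The genes named were fixed by a rule before the data were examined. They are all measured members of the proteasome and cell division lists; the 8 largest rises and 8 largest falls with a product description, and the 3 of each without one, among genes with an adjusted p under 0.05, at least 20 counts per library on average and no overlap between the groups; and the 2 members with the smallest p of every other list that passed the set test or had at least 3 changed members. The rule also covers CCTF1 itself where a file or label names its gene, and none does. Genes named outside the rule are said to be chosen after their values were seen. Of the 52 genes named by the rule, 22 overlap another gene of the table by at most 47 bases, 9 of them a gene of the other strand, whose reads cannot be told apart without the counter's strand setting.

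The edgeR test was checked on simulated counts drawn from the means and library sizes of the 2409 genes, with 200 genes changed in each of 5 simulations. It called 60% of the genes changed 2-fold, 96.4% of those changed 4-fold and 0.362% of the unchanged genes, and 4.78% of its calls were unchanged genes. The list test called 20 of 20 lists of 20 genes moved 1.5-fold and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. In the data, the lists that passed had estimated correlations from 0.0625 to 0.273, so the simulation does not show how often such lists pass falsely.

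Alternatives were DESeq2 size factors, library totals only, no filter on low counts, at least 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, structural RNAs left out, each library left out in turn, and thresholds of 2-fold and of an adjusted p under 0.01. Added after the data were seen were limma on FPKM computed from the counts (pseudocounts of 1 and 0.1, and a mean FPKM of at least 10), lists without accidental spelling matches, structural RNAs left out of the lists, and the second principal component as a covariate. Plots were drawn with matplotlib.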

Results

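RNA abundance was measured by sequencing in Saccharolobus islandicus REY15A, a thermoacidophilic archaeon of hot acidic springs that grows aerobically and divides with an ESCRT-type machinery. The 6 samples form 2 groups of 3. The CCTF1_OE group carried the expression plasmid pSeSD with the transcription factor CCTF1, and the control group carried the plasmid without it. Both were under arabinose, the sugar that switches on the plasmid's promoter. Cultures were started at an OD600 of 0.05 and collected after 12 h at an OD600 of about 0.2. The CCTF1_OE libraries held 3055119, 2980134 and 2891373 counts in replicates 1, 2 and 3, and the control libraries held 3691143, 3167274 and 2952497. Of 2721 genes in the table, 2409 had enough counts to be tested. Levels are given below as CPM (counts scaled to a common library size, edgeR's unit), as mean ± SD with n = 3 per group, and positions lie on the REY15A chromosome (assembly ASM18955v1).

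The comparison asks which genes differ in abundance when CCTF1 is overexpressed, and the series title names the proteasome and cell division as its subjects. The largest rise was that of the gene for Dps, a ferritin-like protein that binds DNA and stores iron, and the largest fall among described genes was that of GlcS, the sugar-binding protein of the glucose ABC transporter. Dps was 35.9-fold higher and GlcS 18-fold lower in CCTF1_OE than in control. The gene of PAN, the ATPase that unfolds substrates and feeds them into the proteasome, was 8.38-fold lower. In all, 261 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 118 of them higher and 143 lower. A change of at least 2-fold was found for 87 of the higher and 97 of the lower genes. The 2 groups did not overlap for 257 of the 261 genes, and for 716 (29.7%) of all tested genes. Chance gives 10% only as an average over all equal splits of the libraries. Genes vary together across libraries, so a single arbitrary split can lie far from that average. The excess over 10% therefore cannot by itself set the real split apart. At an unadjusted p under 0.05 in edgeR the real split gave 575 genes and the highest other split 475. The median gene length was 561 bases for the higher genes, 1032 for the lower and 750 for all tested genes, and across genes the log2 fold change and length had a Spearman rho of -0.119, genes not being independent replicates. The count of 261 became 131 without CCTF1_OE replicate 1 (66 higher, 65 lower) and 150 without CCTF1_OE replicate 2 (74 and 76). It became 120 without control replicate 1 (55 and 65). Control replicate 2 stood apart from the other control libraries on the second principal component, and 344 genes passed without it, 163 higher and 181 lower.

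**Figure D1:**
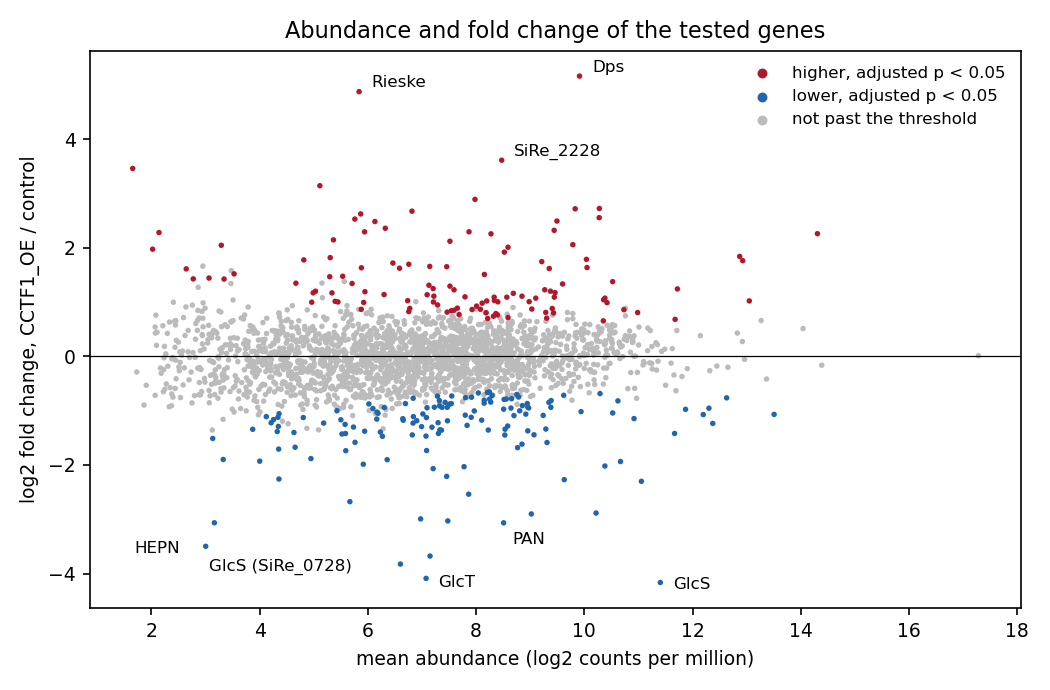
Each point is 1 of the 2409 tested genes, placed by its mean abundance in log2 CPM (horizontal) and its log2 fold change of CCTF1_OE over control (vertical), with 3 libraries per group. Red marks the 118 genes that were higher and blue the 143 that were lower at an adjusted p under 0.05. Dps lies at 5.16 and GlcS at -4.17.

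Of the 6 measured proteasome genes, 1 fell and 5 did not pass the test. PAN (SiRe_1726, positions 1599002 to 1600183, minus strand) had 77.4 ± 3.71 CPM in CCTF1_OE and 649 ± 187 CPM in control (log2 fold change -3.07, SE 0.25, adjusted p = 7.07e-06). The 3 subunits of the proteolytic core and the 2 assembly chaperones gave no call. The alpha subunit gene psmA (SiRe_1271) had a log2 fold change of 0.52 with a 95% interval of 0.11 to 0.94 (adjusted p = 0.108). It passed with the second principal component as a covariate (0.51, adjusted p = 0.0126). That component comes from the same counts, so a call with it is no independent support. The beta subunit genes had -0.05 (SiRe_1237, interval -0.68 to 0.57) and 0.23 (SiRe_1720, -0.25 to 0.71). The sign of SiRe_1237 changed without CCTF1_OE replicate 1 (0.05), CCTF1_OE replicate 3 (0.03) and control replicate 2 (0.27). The chaperone genes had 0.08 (SiRe_1163) and 0.30 (SiRe_1724). The list as a whole did not pass the set test (adjusted p = 0.891), and its median (0.15) and mean (-0.33) differ in sign. Adjusted over the list alone, 0 were higher and 1 lower. PAN kept its call in all alternatives run, with log2 fold changes from -3.22 to -2.79.

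Among the 6 genes of the Cdv machinery, which forms and constricts the ESCRT-III ring at division, 1 rose and 5 did not pass the test. The gene that rose encodes a CdvB1/B2-type ESCRT-III protein (SiRe_1550, positions 1442392 to 1443153, minus strand), with 11346 ± 1924 CPM in CCTF1_OE and 5587 ± 2069 CPM in control (log2 fold change 1.02, SE 0.26, adjusted p = 0.0262). The other CdvB1/B2-type gene, SiRe_1200, had a log2 fold change of 0.43. The values were 0.49 for cdvA, 0.46 for cdvB, 0.27 for cdvC, the gene of the disassembly ATPase, and -0.39 for cdvB3. The list did not pass the set test (adjusted p = 0.17), and adjusted over the list alone, 1 were higher and 0 lower. SiRe_1200 passed without control replicate 2 (0.84, adjusted p = 0.00766), and cdvA (0.92, 0.0291) and cdvB (0.84, 0.0308) passed without control replicate 3. With the replicate number as a block cdvA passed (0.58, 0.0467), and with the second principal component as a covariate cdvA (0.57, 0.0123), SiRe_1200 (0.47, 0.0219) and cdvB (0.51, 0.028) passed. The component comes from the same counts and takes up spread within the groups, and 722 of the tested genes passed with it in place of 261. Calls made with this covariate are therefore no independent support. The call of SiRe_1550 was lost without CCTF1_OE replicate 1 (adjusted p = 0.112), without CCTF1_OE replicate 2 (0.104), without control replicate 1 (0.13) and without control replicate 3 (0.0824), and by limma on FPKM computed from the counts (0.0616). The gene overlaps SiRe_1549 on the other strand by 47 bases, and reads shared between the 2 CdvB1/B2-type genes were not examined.

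**Figure D2:**
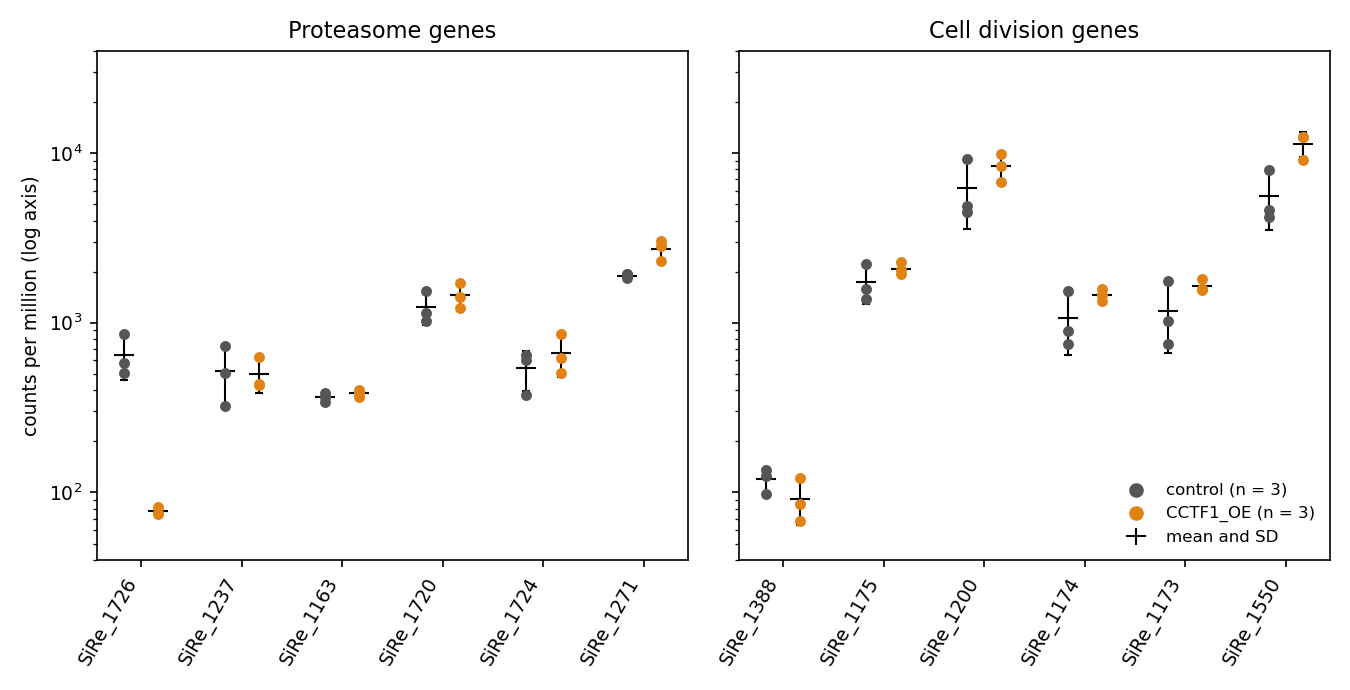
CPM on a log axis of the 6 proteasome genes (left) and the 6 cell division genes (right) in each library, in grey for control (n = 3) and orange for CCTF1_OE (n = 3). The horizontal marks and bars are means and SDs. For PAN (SiRe_1726) the CCTF1_OE libraries lie at 74.7, 76 and 81.6 CPM, and the lowest control library at 509 CPM.

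In the list of oxidative stress and metal genes, 2 of 13 members rose, 11 did not pass, and adjusted over the list alone, 4 were higher and 1 lower. The list passed the set test as higher (camera, adjusted p = 0.0213), and did not pass with an estimated correlation (adjusted p = 0.657) or with fry (0.0591). Its call was also lost without CCTF1_OE replicate 1 (adjusted p = 0.0521) and without control replicate 1 (0.066). The higher and lower members numbered 4 and 1 with the replicate block and 4 and 1 with DESeq2. Its member dps (SiRe_0453, positions 418965 to 419546) rose from 52.2 ± 14.7 to 1872 ± 339 CPM (log2 fold change 5.16, SE 0.29, adjusted p = 9.29e-07), and its member for a rubrerythrin (SiRe_2563), a peroxide-scavenging iron protein, rose by 2.26 on the log2 scale. The Rieske iron-sulfur protein gene SiRe_0454, next to dps and a member of the respiratory chain list, had a log2 fold change of 4.88 (SE 0.38), on 37 counts summed over the control libraries and 962 over the CCTF1_OE libraries. A gene of the VIT1/CCC1 family of iron and manganese transporters (SiRe_2636), from the list of other membrane transport, had 2.89.

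In the list of other membrane transport genes, 2 of 160 members rose and 38 fell, and 120 did not pass, while adjusted over the list alone, 5 were higher and 48 lower. The list passed the set test as lower (adjusted p = 1.65e-08), and did not pass with an estimated correlation (adjusted p = 0.657). The genes glcS, glcT, glcU and glcV (SiRe_2180, SiRe_2179, SiRe_2178 and SiRe_2177) form 1 cluster between positions 2010323 and 2015094 and encode the binding protein, the permeases and the ATPase of the glucose transporter. Their log2 fold changes were -4.17, -4.09, -3.68 and -3.03, and glcS itself went from 5131 ± 632 to 286 ± 63.5 CPM (adjusted p = 9.29e-07). A further gene annotated as glcS at another locus, SiRe_0728, fell by 3.83 on the log2 scale. Whether it shares reads with SiRe_2180 was not examined. Without CCTF1_OE replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, the lower members numbered 18, 22, 24, 18, 39 and 36 and the higher 2, 3, 2, 3, 4 and 2. The glucose transporter genes above do not match the name patterns of the list of sugar transport and glycoside hydrolysis. That list, which therefore leaves out their falls, did not pass the set test (adjusted p = 0.677). In it, 2 of 15 members rose. Its median (-0.22) and mean (0.16) differ in sign. The genes of this list that rose, chosen after their values were seen, encode a Sip1-related alpha-galactosidase (SiRe_2123, log2 fold change 1.62) and an alpha-mannosidase (SiRe_2237, 2.30).

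The list of genes for UV-inducible pili and DNA import passed the set test as higher (adjusted p = 0.000726), and did not pass with an estimated correlation (adjusted p = 0.657) or with fry (0.0591). These genes encode pili that aggregate cells and a system that takes up DNA from them. Of 9 members 6 rose, and the count was the same adjusted over the list alone. The gene of a secretion ATPase in the pilus cluster (SiRe_1879) had 259 ± 53.1 CPM in CCTF1_OE and 106 ± 15.3 CPM in control (log2 fold change 1.29, SE 0.23, adjusted p = 0.00328). The gene cedA (SiRe_1317), for the import channel, had a log2 fold change of 1.16 (adjusted p = 0.00449). The further members were chosen after their values were seen. The import genes cedA1 (SiRe_1316, 1.23), cedA at SiRe_2100 (1.14) and cedB (SiRe_1857, 0.98) also rose. Of the pilus genes, upsA (SiRe_1881, 1.20) rose with groups that overlapped. The pilus genes upsX (0.70, adjusted p = 0.264), upsF (0.13, 0.844) and upsB (0.15, 0.866) did not pass. Without each library in turn, in the order CCTF1_OE replicates 1, 2 and 3 and control replicates 1, 2 and 3, the members that rose numbered 3, 4, 4, 2, 6 and 3. The list of archaellum and pili, which shares the pilin gene upsA, had 2 of 9 members higher, numbering 1, 3, 2, 1, 2 and 1 in the same order, and did not pass (adjusted p = 0.463).

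The list of ribosomal protein genes passed the set test as higher (adjusted p = 0.00398), and did not pass with an estimated correlation (adjusted p = 0.657), with fry (0.119) or without control replicate 2 (0.0652). Of 67 members 4 rose, 1 fell and 62 did not pass, and the median log2 fold change was 0.25. Those for S27e (SiRe_1044) and L24 (SiRe_1299) had log2 fold changes of 1.09 and 1.07. S27e lost its call without control replicate 1 (adjusted p = 0.0502), and L24 without CCTF1_OE replicate 1 (0.0759) and without control replicate 1 (0.0692). Leaving out CCTF1_OE replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, 1, 3, 4, 0, 6 and 9 of its members rose and 0, 1, 0, 0, 1 and 2 fell. The higher and lower members numbered 13 and 2 with the replicate block and 7 and 2 with DESeq2. Ribosomal RNA took 2.32 ± 0.168% of all counts in CCTF1_OE and 1.12 ± 0.584% in control (mean ± SD, n = 3). An exact permutation test of that share, two-sided, gave p = 0.1, the smallest that 3 against 3 allow. The 16S rRNA gene (SiRe_r0002) had a log2 fold change of 1.84 (SE 0.31, adjusted p = 0.00256). The 23S rRNA gene (SiRe_r0001), chosen after its values were seen, had 0.66 (adjusted p = 0.199), with groups that overlapped, and passed without control replicate 2 (1.13, adjusted p = 0.000555). With so small a share of the counts, whether the rRNA values follow the rRNA content of the cells was not tested. A tRNA-Ser gene (SiRe_t0035) had -1.51 on 36 counts in CCTF1_OE and 121 in control. The tRNA-Ser call was lost without CCTF1_OE replicate 1 (0.2), CCTF1_OE replicate 3 (0.125), control replicate 1 (0.223) and control replicate 2 (0.0521), and with limma-voom (0.0513). In the list of structural RNAs, 1 of 24 members rose and 2 fell, the latter numbering 0, 2, 1, 0, 1 and 3 and the former 1, 1, 1, 1, 2 and 1 in the same order of libraries left out. It did not pass the set test (adjusted p = 0.151), except without CCTF1_OE replicate 2 (0.0167).

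Changed metabolic genes were spread over several lists, whose counts are to be read against 118 higher and 143 lower among all 2409 tested genes. In the list of central carbon metabolism, 3 of 52 members rose and 6 fell, and 5 of the 6 that fell are the glucose transporter genes, which match the list by their name. With such accidental matches left out, 3 of 39 members rose and 1 fell, the median was 0.0005, and the set test gave an adjusted p of 0.967. All other values given for this list keep these matches. A glucose 1-dehydrogenase gene (SiRe_2243), for the entry step of glucose breakdown, rose to 2155 ± 283 CPM from 326 ± 36.2 CPM (log2 fold change 2.73, SE 0.21, adjusted p = 5.88e-06). In the list of the respiratory chain and ATP synthase, 1 of 42 members rose and 8 fell. The largest fall was that of a gene annotated as the quinone methyltransferase UbiG (SiRe_1791, -2.68), which is not a subunit of the chain. Other members that fell, chosen after their values were seen, encode cytochrome c oxidase subunits I (SiRe_2267) and II (SiRe_2271). The Rieske protein gene SiRe_2269 and the cytochrome b gene SiRe_2270, between them and chosen likewise, also fell. These members lie in a run of 6 lower genes, SiRe_2267 to SiRe_2272, with a median log2 fold change of -1.04. The run also holds a sulfocyanin gene (SiRe_2268) outside the list. In amino acid synthesis 1 of 36 members rose and 4 fell, among them argininosuccinate synthase (SiRe_1372, -1.34) and ketol-acid reductoisomerase (SiRe_0753, -1.99), a step toward branched-chain amino acids. In pyrimidine and purine synthesis 2 of 27 members rose and 2 fell. There, orotate phosphoribosyltransferase (SiRe_1392) rose by 1.62 and CTP synthase (SiRe_1805) by 1.09 on the log2 scale, the latter with adjusted p = 0.0505 without control replicate 1. In fatty acid and CoA-linked catabolism 2 of 35 members rose and 2 fell, and in lipid and S-layer genes 2 of 15 members fell. A 3-hydroxyacyl-CoA dehydrogenase gene (SiRe_1366) had 1.19 and a thiolase gene (SiRe_2134) -1.30. Without CCTF1_OE replicate 1 their adjusted p were 0.0709 and 0.106, and the thiolase call was also lost without CCTF1_OE replicate 3 (0.0624) and without control replicate 1 (0.115). None of these 6 lists passed the set test (adjusted p from 0.0987 to 0.852), except central carbon metabolism (0.0167) and the respiratory chain (0.0312) without CCTF1_OE replicate 2 and the respiratory chain (0.0492) without control replicate 3. Without CCTF1_OE replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, the higher and then the lower members numbered 1, 1, 1, 1, 3 and 2 and 5, 6, 5, 5, 7 and 6 in central carbon metabolism. In that order, 2, 4, 4, 3, 8 and 8 respiratory genes fell, and 0, 0, 0, 0, 1 and 1 amino acid synthesis genes rose and 2, 2, 3, 2, 6 and 2 fell. In pyrimidine and purine synthesis 2, 2, 2, 1, 2 and 3 rose and 0, 0, 1, 0, 7 and 0 fell, in fatty acid catabolism 0, 1, 2, 1, 3 and 1 rose and 0, 1, 0, 0, 1 and 3 fell, and of the lipid and S-layer genes 0, 2, 1, 0, 2 and 2 fell. With the replicate block the higher and lower members numbered 3 and 10 in central carbon metabolism, 4 and 4 in fatty acid catabolism and 3 and 4 in pyrimidine and purine synthesis. With library totals only they were 1 and 3 in fatty acid catabolism and 2 and 4 in pyrimidine and purine synthesis, and with DESeq2 2 and 4 in the latter.

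Among regulators and proteins of information processing, the naming rule took the 2 regulator genes with the smallest p. A helix-turn-helix protein (SiRe_1000) rose to 1630 ± 52.4 CPM from 472 ± 87.4 CPM (log2 fold change 1.79, SE 0.21, adjusted p = 0.000145), and a PadR-type repressor (SiRe_0323) had 1.03, a call lost without CCTF1_OE replicate 1 (adjusted p = 0.0894) and without control replicate 1 (0.0762). In the list of transcriptional regulators, 4 of 99 members rose and 1 fell, where 118 of all 2409 tested genes rose and 143 fell. Chosen after their values were seen, SIRE_RS13660 (1.61, adjusted p = 0.0415) and SiRe_2511 (1.44, 0.0372) rose more than the PadR gene. The member that fell was SiRe_0077 (-0.94). In the toxin-antitoxin list, 3 of 38 members rose and 2 fell. A HEPN protein of that list (SiRe_0902, -3.50) and its nucleotidyltransferase neighbour outside it (SiRe_0903, -3.07) gave only 10 and 15 counts summed over the CCTF1_OE libraries, and 132 and 146 over the control libraries. A PIN-domain gene (SiRe_1477) had 1.00, lost without CCTF1_OE replicate 1 (0.0851) and without control replicate 1 (0.0748). In protein folding and other proteolysis, 1 of 56 members rose and 6 fell, the 2 with the smallest p being signal peptidase I (SiRe_1168, -1.35) and a protease with a pro-enzyme activation domain (SiRe_0965, -1.07). None of these 3 lists passed the set test (adjusted p = 0.134, 0.568 and 0.852), except the regulators without CCTF1_OE replicate 2 (0.0206). Leaving out in turn CCTF1_OE replicates 1, 2 and 3 and control replicates 1, 2 and 3, the regulators that rose numbered 1, 2, 2, 2, 8 and 3 and those that fell 0, 0, 4, 0, 2 and 0. In toxin-antitoxin genes 0, 1, 2, 0, 2 and 2 rose and 1, 1, 1, 1, 1 and 2 fell, and in protein folding 0, 1, 0, 0, 4 and 2 rose and 3, 3, 5, 3, 7 and 3 fell. With the replicate block the higher and lower members numbered 7 and 10 in protein folding, 10 and 3 in regulators and 5 and 3 in toxin-antitoxin genes, and with DESeq2 3 and 9, 7 and 2 and 4 and 2. With library totals only, 1 and 2 toxin-antitoxin genes were higher and lower, so that the more frequent direction turned.

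The remaining lists had few changed members, and those named here were chosen after their values were seen. In DNA replication, 2 of 26 members rose: an ORC1-type initiator (SiRe_1231, 2.01) and a ribonucleoside-diphosphate reductase (SiRe_1156, 1.76). In chromatin proteins, 1 of 6 members rose and 1 fell, namely the gene of the DNA-binding protein Ssh7b (SiRe_0668, 2.53) and that of Alba1 (SiRe_1125, -1.23). In DNA repair, 1 of 25 members fell, the nuclease gene nurA (SiRe_0094, -0.95). In the transcription machinery, 1 of 25 members rose and 1 fell, an RNA polymerase family protein (SiRe_1402, 1.14) and RNA polymerase subunit D (SiRe_1921, -0.85). In the tRNA synthetases and translation factors, 1 of 37 members rose, initiation factor aIF-1A (SiRe_0172, 1.03). In mobile elements, 1 of 22 members rose, an IS5 family transposase (SIRE_RS14500, 1.42). In CRISPR-Cas, edgeR called 0 of 24 members, as did DESeq2 and limma-voom, while 4 had an unadjusted p under 0.05 and 2 fell without control replicate 2. With the replicate block 1 CRISPR-Cas member was higher and 2 were lower, and the higher and lower members numbered 4 and 2 in the transcription machinery, 3 and 1 in the translation list and 3 and 2 in DNA replication. With DESeq2 they were 3 and 2, 2 and 1 and 2 and 1. None of these 7 lists passed the set test (adjusted p from 0.108 for the transcription machinery to 0.677 for DNA repair), except the transcription machinery and the translation list without control replicate 3 (0.0492 each). The call of nurA was lost without CCTF1_OE replicate 2 (0.0668) and control replicate 1 (0.0537), with adjusted p in brackets, and that of aIF-1A without CCTF1_OE replicate 1 (0.0835), CCTF1_OE replicate 2 (0.0575) and control replicate 1 (0.1). RNA polymerase subunit D lost its call without CCTF1_OE replicate 1 (0.0733), CCTF1_OE replicate 2 (0.105), CCTF1_OE replicate 3 (0.0653) and control replicate 1 (0.134). The transposase lost it without CCTF1_OE replicate 1 (0.193), CCTF1_OE replicate 2 (0.111), control replicate 1 (0.157) and control replicate 3 (0.0815), and with limma-voom (0.0537). Counts in the same lists also grew without control replicate 2 or 3, to at most 3 members in either direction.

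Adjusted over the list alone, the counts of higher and lower members were 2 and 6 in protein folding and other proteolysis, 1 and 2 in the transcription machinery, 2 and 0 in transcriptional regulators, 2 and 1 in chromatin proteins, 3 and 1 in archaellum and pili. They were 1 and 3 in structural RNAs, 1 and 9 in the respiratory chain, 2 and 3 in pyrimidine and purine synthesis, 3 and 1 in sugar transport. No member of the translation factor and mobile element lists passed that way, and the counts of the lists not named in these sentences were the same under both adjustments, apart from those given with their lists. The median and the mean log2 fold change differ in sign for protein folding (0.12 and -0.002), lipid and S-layer genes (0.10 and -0.08), DNA replication (-0.03 and 0.12) and fatty acid catabolism (-0.02 and 0.01).

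Genes with no product description moved as well. The 3 largest rises among them were those of SiRe_2228 (3.61), SiRe_2663 (2.63) and SiRe_0149 (2.49), and the 3 largest falls those of SiRe_0058 (-1.71), SiRe_1313 (-1.42) and SiRe_0450 (-1.42). Other described genes with large rises were those annotated as glycogen debranching enzyme GlgX (SiRe_0487, 3.14), an aldo/keto reductase (SiRe_2229, 2.72), a DUF4434 protein (SiRe_2238, 2.68) and a xanthine dehydrogenase family protein (SiRe_2234, 2.56). SiRe_0487 is 315 bases long and had 70 counts summed over the control libraries and 536 over the CCTF1_OE libraries. The call of SiRe_1313 lies at the threshold (adjusted p = 0.0492), and was lost with library totals only (0.0643), with DESeq2's size factors (0.0562), without CCTF1_OE replicate 1 (0.142) or 2 (0.134), and without control replicate 1 (0.247) or 3 (0.0812). It was also lost with at least 50 counts in 3 libraries (0.0524) and with limma on FPKM computed from the counts (0.0536 to 0.055).

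**Figure D3:**
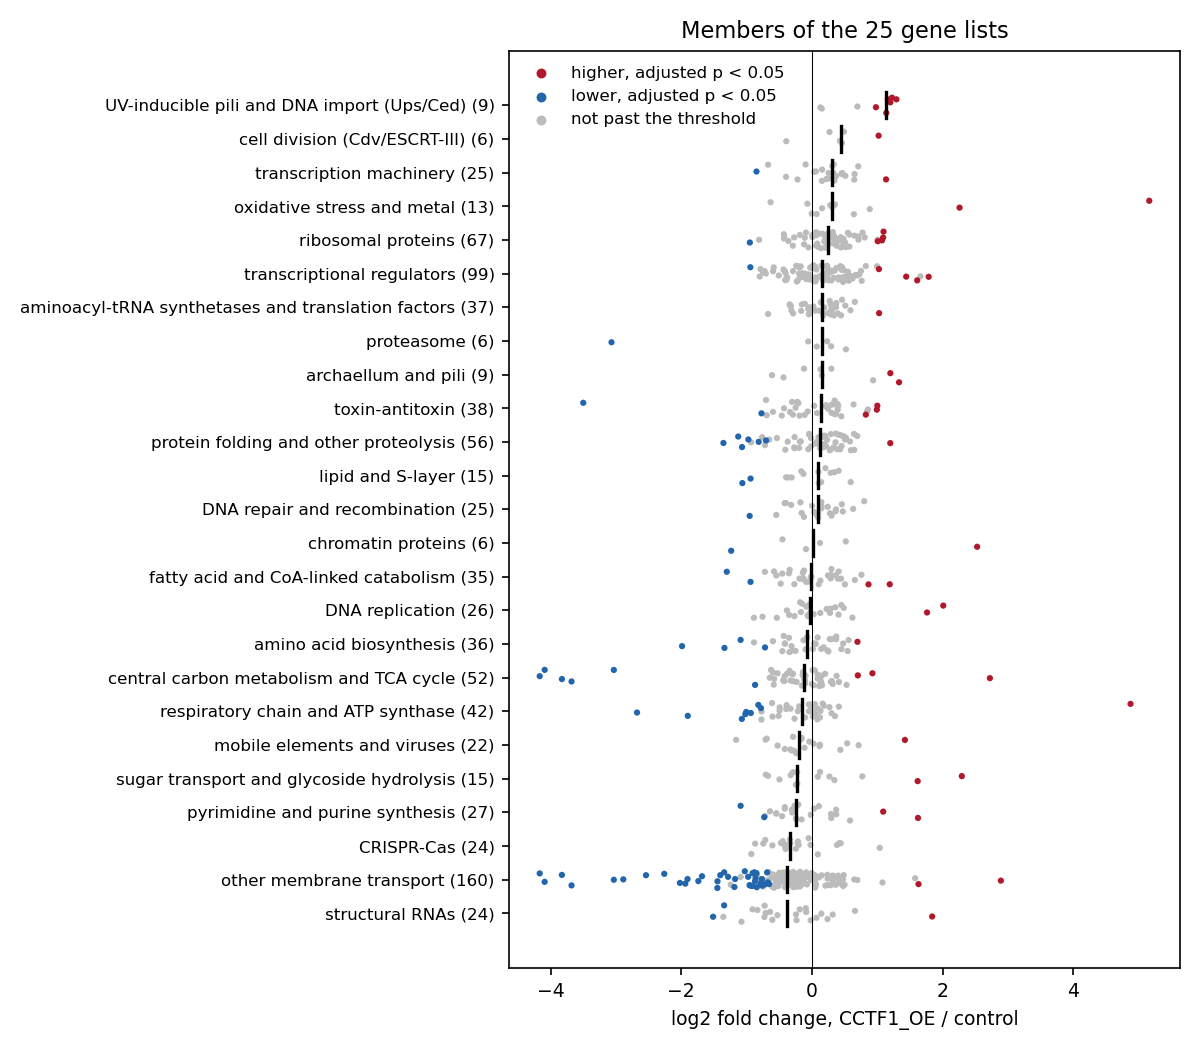
Log2 fold change of CCTF1_OE over control (horizontal) for every tested member of the 25 gene lists, with the number of tested members in brackets and lists ordered by their median (black bars). Red and blue points are members higher and lower at an adjusted p under 0.05, and grey points did not pass. The highest median is that of the UV-inducible pili and DNA import list (1.14) and the lowest that of the structural RNAs (-0.38).

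Changed genes lay side by side on the chromosome, and the runs named here were chosen after their values were seen. Among the tested genes in chromosome order, 74 adjacent pairs were called in the same direction, where 10000 permutations of the order gave 14.2 on average and 29 at most (permutation p = 1e-04, the smallest they can give). The permutations treat neighbouring genes as independent. Neighbours can share a transcript and some overlap, so the excess does not tell what changed them. The pairs numbered 36, 39, 51, 37, 100 and 61 without CCTF1_OE replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn. All 13 tested genes from SiRe_2227 to SiRe_2243 (positions 2071431 to 2092824) rose, with a median log2 fold change of 2.30, and 12 of them passed without CCTF1_OE replicate 1, CCTF1_OE replicate 2 or control replicate 1. Of the 20 tested genes from SiRe_2119 to SiRe_2141 (positions 1953362 to 1978934), 14 fell and 1 rose, and 10, 9, 11, 10, 14 and 12 fell with the libraries left out in the same order. They include genes of pentose breakdown, arabinonate dehydratase (SiRe_2125, -1.62) and 2,5-dioxopentanoate dehydrogenase (SiRe_2130, -2.30), and an MFS transporter gene (SiRe_2128, -2.89). On the other side of PAN, 72 bases away on the plus strand, the gene of the transcription cofactor aMBF1 (SiRe_1727) fell from 287 ± 134 to 62 ± 17.5 CPM (log2 fold change -2.21, SE 0.35, adjusted p = 0.00171), and the next gene, for the GTPase HflX (SiRe_1728), had -2.03. The genes that flank these 3, SiRe_1725 and SiRe_1729, had -0.23 and -0.04 and did not pass. Their signs changed without control replicate 3 (0.32 and 0.29), and that of SiRe_1729 also without CCTF1_OE replicate 2 and with limma-voom (0.01 each).

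**Figure D4:**
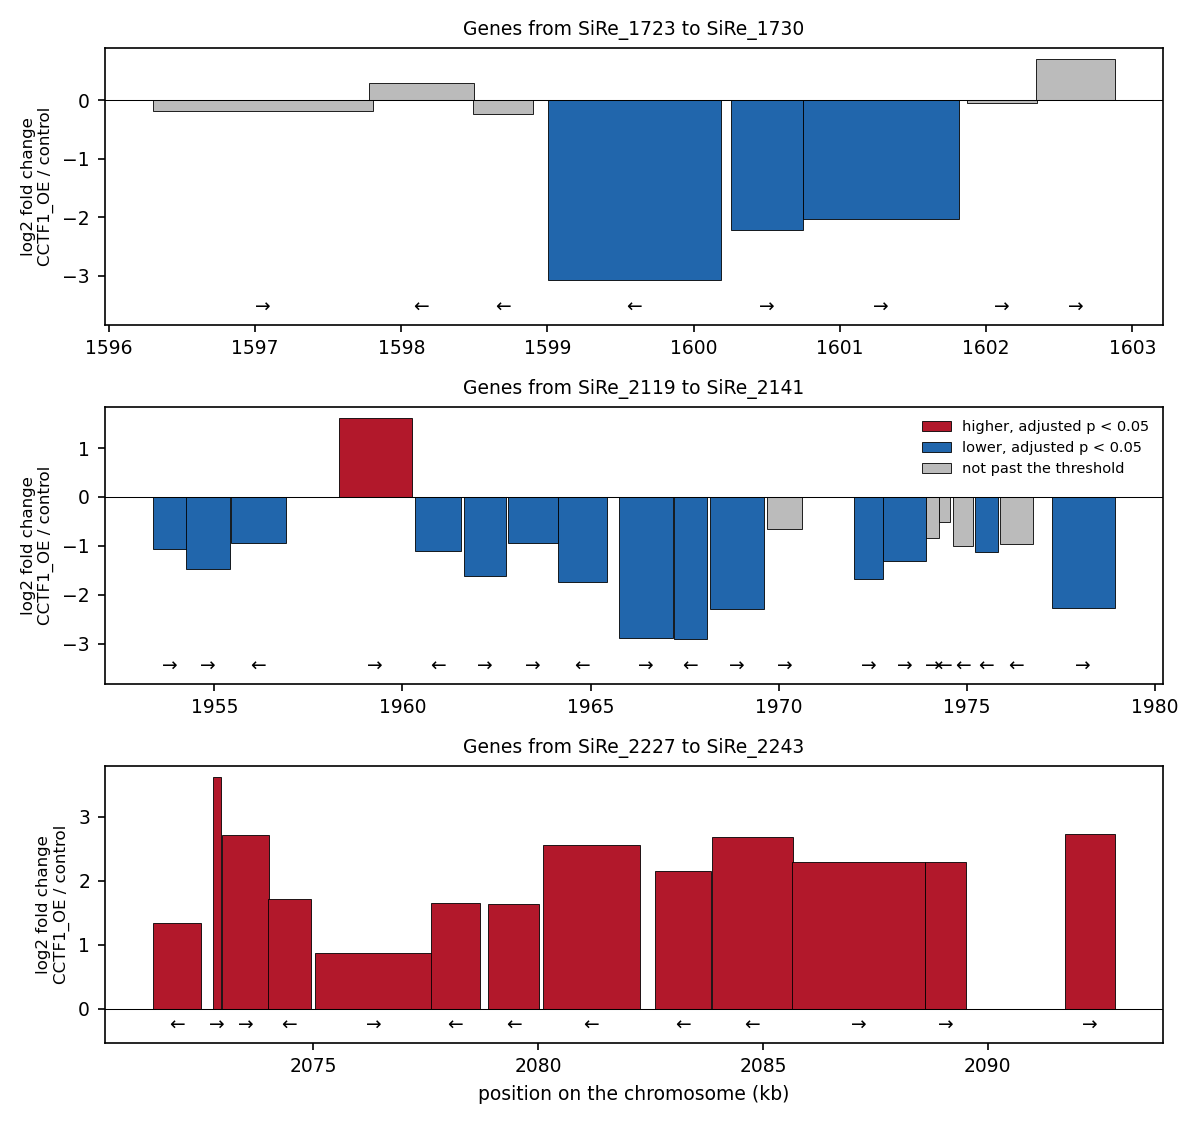
Log2 fold change of CCTF1_OE over control (vertical, 3 libraries per group) for the tested genes of 3 chromosome windows, drawn to scale by position in kb, with arrows for the strand. Red and blue bars are genes higher and lower at an adjusted p under 0.05, and grey bars did not pass. PAN is the bar at -3.07 in the top window, and all 13 genes of the bottom window lie above 0.

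The authors' deposited table of this comparison counts 168 genes higher and 196 lower at an adjusted p under 0.05, with 94 and 103 of them changed at least 2-fold. All 261 genes called here are among the 364 in the authors' deposited table.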

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

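The genes called and the lists passing the set test were recomputed under the alternatives, of which the second principal component as a covariate, limma on FPKM computed from the counts, the structural RNAs left out of the lists and the lists without spelling matches were chosen after the data were seen. The planned limma test on deposited FPKM was not run, as no FPKM column was used here. The 261 calls (118 higher, 143 lower) became 464 (218, 246) with the replicate block, 722 (345, 377) with the covariate and 115 (54, 61) at an adjusted p under 0.01. All 261 calls were among the 464. Deviations of same-numbered libraries from their group means correlated at -0.348, 0.523 and 0.389, so the numbers were not taken to pair the samples, and not every library correlated best with its own number. Leaving out 1 library gave 120 to 344 calls, 55 to 163 higher and 65 to 181 lower, with fewer samples in each fit. The other counts lay within 1.5 times, and the cause of these differences was not otherwise tested. The 4 lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05), 2 with fry and 3 to 8 without 1 library. With fry, which sets a list against no other genes, the proteasome list with PAN passed (0.023) and the lists of ribosomal proteins (0.119), UV-inducible pili (0.0591) and oxidative stress (0.0591) did not. Of 931 comparisons of the 52 named genes, 886 kept direction and side, 34 lost and 8 gained the call, and 3 changed direction: psmB (SiRe_1237), which has no call, ranged from -0.29 to 0.27 without 1 library. Of the 42 called, 32 kept the call in every alternative. Without 1 library, 8 lists that did not pass changed direction in some fits, with adjusted p over the 6 fits of 0.779 to 0.992 for the proteasome, 0.762 to 0.986 for protein folding (0.963 with fry, which also changed its direction), 0.151 to 0.992 for DNA replication, 0.458 to 0.992 for DNA repair, 0.152 to 0.785 for mobile elements, 0.376 to 0.976 for fatty acid catabolism, 0.163 to 0.99 for pyrimidine and purine synthesis and 0.7001 to 0.992 for lipid and S-layer genes. At these depths the test on simulated counts (60% of 2-fold and 96.4% of 4-fold changes called) missed 2-fold changes more often than 4-fold ones.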

Other observations

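Tests on these patterns were chosen after the results were seen, except the thinning of the libraries to 1 depth, whose outcome was not known when it was written down. Beyond the lists, further neighbours changed together, chosen after their values were seen. All 3 tested genes from SiRe_2561 to SiRe_2563 rose, also without each library in turn, with SiRe_2562, an iron-sulfur protein related to heterodisulfide reductase, at 1.64 beside the rubrerythrin gene at 2.26. A pair of adjacent acyl-CoA carboxylase subunit genes fell, SiRe_0254 to 27.8 ± 2.9 from 222 ± 16.4 CPM (log2 fold change -2.99, SE 0.23, adjusted p = 5.88e-06) and SiRe_0253 by 1.88 on the log2 scale. In tested genes of at most 432 bases, the median deviation from the mean of the libraries was 0.02, 0.04 and 0.12 (log2) in CCTF1_OE replicates 1, 2 and 3 and -0.11, 0.01 and -0.05 in control replicates 1, 2 and 3. A length bias in library making that differs between the groups was not separated from the group difference and stays open.

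The count of 261 was set against other splits of the samples. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, and the highest of the others gave 0 with edgeR. At an unadjusted p under 0.05 the real split gave 575 and the highest other 475, and with DESeq2 and limma-voom the highest others gave 129 and 0 calls. With 10 splits the share is never under 0.1, so it cannot fall under 0.05.

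The first pattern weighed is the fall of PAN, at a log2 fold change of -3.07, while no other proteasome gene passed. The exception is psmA (SiRe_1271), higher by 0.51 (adjusted p = 0.0126) with the second principal component, taken from the same counts, as a covariate. The value of PAN stayed at or below -3.06 under the 4 other scalings, so the choice among these hardly matters for it. Under them the median log2 fold change of the tested genes lay between -0.071 and -0.006. They differ too little to have moved PAN far, so a larger scaling error could not be weighed this way. A single library is argued against, as the value of PAN stayed at or below -2.79 without each library in turn, with an adjusted p of at most 0.000166. A change shared across the 72 bases between PAN and the divergent pair stays open: 2 of the 2 genes of that pair fell, but the pair was picked because it fell, its genes overlap by 4 bases on 1 strand, and neighbours often changed together, so this does not count for it. Whether CCTF1 acts at that region directly was not tested.

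The second pattern is the second principal component, 29.9% of the variance, on which CCTF1_OE replicates 1 and 2 and control replicate 2 lie on the positive side and the other libraries on the negative side. Library size stays open. With every library thinned to 2891373 counts the component held 29.9% of the variance, with 6 of 6 libraries on their former side. The totals reach only 3691143 and the levels were already scaled for them, so thinning could hardly have lowered that share. Over the 6 libraries its correlation with total counts did not pass (Pearson's r = -0.0517, exact permutation p = 0.971, and Spearman's rho = 0.6, exact permutation p = 0.242). Without the 2 libraries farthest from the median r was 0.814, and so few libraries cannot exclude a relation. Gene length is argued against, with a Spearman rho of -0.0211 across genes between loading and gene length, genes not being independent replicates. Growth or cell cycle state may contribute and cannot be told apart from a shared day or batch, which the labels do not give: the median loading of the cell division list lay at percentile 4.53 of 10000 random lists matched on expression, lists that passed between the groups lay at 0.32 (UV-inducible pili), 24.9 (ribosomal proteins), 97.2 (oxidative stress) and 99.9 (other membrane transport), and lists that did not pass lay as far out, at 0.3 (regulators), 0.97 (pyrimidine and purine synthesis), 2.49 (DNA replication), 99.9 (fatty acid catabolism) and 100 (mobile elements). With the component, which comes from the same counts, as a covariate, 722 genes passed in place of 261.

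The third pattern is that the overexpressed gene could not be checked in the counts, because no label or file names the locus of CCTF1. A mislabelled library or a swap between the groups is argued against, since 6 of 6 libraries correlated best with a library of their own group. An exchange of all labels of both groups could not be excluded: the locus SiRe_0800, which has the number in the names of the CCTF1_OE columns and was chosen after its value was seen, had a log2 fold change of -0.40 (adjusted p = 0.44). Whether it is CCTF1 is not stated, and reads of a plasmid copy may not have been counted at the chromosomal locus. Directions in the text therefore rest on the sample labels.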
